A study of Rattus norvegicus with 14 samples.

How the data were processed

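Gene expression was measured in neonatal rat ventricular myocytes, beating heart muscle cells isolated from the ventricles of 2-day-old Sprague-Dawley pups and kept in culture. Per the labels' protocols, a pre-plating step removed non-myocytes and the cells were held in serum-free medium before stimulation. Cells received JQ1, a small molecule that displaces BET bromodomain proteins from acetylated chromatin, or its vehicle DMSO. They were stimulated with phenylephrine (PE, 100 µM), an alpha1-adrenergic agonist that makes cultured myocytes hypertrophy. The labels' treatment protocol places JQ1 or DMSO 6 h before PE, whereas the series' design text places PE first, so the order of addition is not settled. The concentration of JQ1 was not given in the sources used here.

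Total RNA was labelled with biotin and hybridised to an Affymetrix rat array, per the labels' protocols. The deposited values are log2 expression values per probe set, and the distributions of the 14 arrays nearly coincide, as they would after normalization between arrays. That the authors normalized them is inferred from the values alone. Summarization, background correction, probe set filtering and the method of normalization were not given in the sources used here. The submitters' processing notes name limma without its role. The table held 20223 probe sets with values from 2.71 to 14.70. Array medians ran from 7.28 to 7.43. No column was left without a sample.

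The probe table gave 1 gene symbol for 18510 probe sets, several for 305 and none for 1402, and 6 more were controls. Symbols were looked up in the rat RefSeq gene table of the GRCr8 assembly: 18461 probe sets matched through the gene identifier and 1 through an accession, and 48 kept the platform's symbol. Where a gene had several probe sets (3797 genes), the one with the highest mean over the 14 arrays was used. This left 13184 genes. Choosing the brightest probe set favours signal well over background, but it can pick one transcript form. Comparing the other probe sets of rule-named genes, contrast by contrast, 232 changed in the same direction past the threshold and 102 without passing. Of the rest, 37 lay in the opposite direction without passing, and 5, all of Atp2a2 or Trdn, passed in the opposite direction. No coordinates were used except the order of genes along chromosomes.

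Groups came from the sample labels: DMSO for 90 min without PE (n = 3), DMSO with PE for 6 h (n = 2), JQ1 with PE for 6 h (n = 3), DMSO with PE for 48 h (n = 3) and JQ1 with PE for 48 h (n = 3). All 14 arrays entered 1 linear model with a mean per group, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 9 residual degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 13184 genes, with a threshold of 0.05. Errors of log2 fold changes are standard errors (SE) from this fit. Nothing in the labels says whether arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Array number limits the precision: the median SE of a log2 fold change was 0.060 for 3 against 3 arrays and 0.068 where the 2 arrays of DMSO with PE at 6 h entered.

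Before the data were examined, 32 gene lists were fixed: 24 of pathways and 8 of cell type markers, covering heart muscle, non-muscle cells of the heart and blood. Of 791 entries, 686 were measured, with 6 to 35 genes per list. Each list was tested with camera of limma, which compares a list with the other genes, using a preset inter-gene correlation of 0.01 and again with a correlation estimated from the data. Its p-values were adjusted over the 32 lists of a comparison. The genes named in the text also follow a rule fixed then. For PE and JQ1 comparisons it takes the 6 genes raised and the 6 lowered with the largest change. These are drawn from genes past the threshold whose arrays do not overlap between groups. For late against early PE it takes 4 each in the same way. For the difference of JQ1 effects it takes 4 each past the threshold, without the condition on overlap. For a described list it takes up to 4 members with the smallest adjusted p in the majority direction and 1 in the other. A fixed panel completes it: Nppa, Nppb, Acta1, Myh7, Myh6, Atp2a2, Ccn2 (listed as Ctgf), Il6, Rcan1, Clcf1, Myc, Hexim1, Thbs1 and Xirp2. The last 2 were not analysed here, and 2 further panel genes are not reported here.

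The fit was tested on simulated data with the real means and spreads, with 50 of 13184 genes changed at each of 4 fold sizes. For JQ1 against DMSO at 48 h it recovered 100% of genes changed 2-fold, 100% at 1.5-fold and 66.0% at 1.25-fold, with 6.63% false among all calls. At 6 h, with 2 DMSO arrays, it recovered 100%, 94.0% and 60.0%, with 7.81% false. For PE at 48 h the values were 100%, 96.0% and 80.0%, with 3.09% false, and for PE at 6 h 100%, 90.0% and 68.0%, with 2.19% false. Genes varied independently in these simulations and few were changed, whereas the real comparisons called 37.2% (PE at 6 h) to 59.6% (JQ1 at 48 h). The adjusted threshold is then less strict, so these shares need not hold for small changes in the real data. Since the PE and JQ1 comparisons share the DMSO with PE arrays, 100 simulations of unchanged groups gave the values that sharing alone produces.

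Alternatives fixed in advance were another spread model, a fit of the compared groups alone, array weights, the replicate number as a block and leaving out dim genes (below the 30th percentile). Others were repeating quantile normalization, centring each array on its median, the mean of a gene's probe sets, leaving out probe sets shared between transcripts, a 2-fold minimum, an estimated correlation for the gene lists, and leaving out each array in turn. Testing the gene lists under both rescalings was added after seeing the data. A pseudocount was not needed because the values were already on the log2 scale. Plots were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3.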

Results

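The series followed cultured neonatal rat heart muscle cells through hypertrophic stimulation with PE, with or without inhibition of the BET proteins by JQ1, at 6 h and 48 h. Expression of 13184 genes was compared across 14 arrays in 5 groups. These were unstimulated DMSO at 90 min (n = 3), DMSO with PE at 6 h (n = 2) and 48 h (n = 3), and JQ1 with PE at 6 h (n = 3) and 48 h (n = 3). Arrays of a group correlated at r of 0.9976 to 0.9986 across probe sets. The first principal component, with 56.8% of the variance, set the 6 JQ1 arrays (scores 28.8 to 34.5) apart from the 8 DMSO arrays (-26.1 to -19.1), and the next, with 23.1%, set the 5 arrays with PE for 6 h (13.7 to 25.3) apart from the others (-24.4 to 0.8). The medians of JQ1 arrays were lower than those of DMSO with PE arrays by 0.085 at 6 h and 0.088 at 48 h on average. The 3' to 5' signal difference of the Gapdh control, a sign of RNA quality, lay between -0.10 and -0.03 on every array, and that of the hexokinase control between 1.10 and 1.55. A group mean below log2 6.23, the dim limit (30th percentile of genes), lies near background, and the size of a change from or to such a group is uncertain. Changes are given as log2 fold changes ± SE of the limma fit with these array numbers. List counts use p-values adjusted over the 13184 genes, and counts adjusted over the list alone were equal unless given.

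The response to 6 h of PE was read against the unstimulated 90 min cells, the arm without PE used here, so PE and time in culture differ together. The orphan nuclear receptor gene Nr4a3 rose 6.79-fold (2.76 ± 0.089) and Rgs2, which limits signalling through Gq-coupled receptors, 5.25-fold (2.39 ± 0.062). The bradykinin receptor gene Bdkrb2 (3.45 ± 0.13) and Ch25h, a sterol hydroxylase (3.13 ± 0.11), rose from dim levels. Lmcd1 (2.44 ± 0.10) and Olr1, a scavenger receptor, also dim before (2.38 ± 0.13), completed the 6 largest rises. The MAP kinase phosphatase gene Ptprr fell to a dim level (-3.06 ± 0.078) and the cardiac gene Lrrc10 fell 6.75-fold (-2.76 ± 0.070), followed by Smim5 (-2.26 ± 0.24), Pik3ip1 (-2.11 ± 0.078), Tox (-1.96 ± 0.12) and Phactr1 (-1.84 ± 0.12). Adjusted p was at most 1.2e-05 for each of these 12 genes. Dimmer probe sets of Bdkrb2 (0.16) and Pik3ip1 (-0.07) did not pass.

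Of the 32 fixed lists, 11 passed at 6 h of PE. Of MYC and ribosome biogenesis genes, 26 of 28 rose and 0 fell, with a median of 0.38 (adjusted p = 6.9e-13, and adjusted p = 0.0521 with an estimated correlation). They included Rrp12 (1.39 ± 0.072), the spermidine synthase gene Srm (0.66 ± 0.048) and Nolc1 (0.60 ± 0.047). Of immediate early genes, 23 of 28 rose and 1 fell (adjusted p = 5.6e-12, and adjusted p = 0.0521 with an estimated correlation), with Fos at 2.14 ± 0.071, Fosl1 at 1.47 ± 0.074 and Ier2 at 1.01 ± 0.057. Hypertrophic marker genes rose as a list: 15 of 19 rose and 0 fell (adjusted p = 8.1e-11, and adjusted p = 0.0521 with an estimated correlation). Members included Fhl1 (0.89 ± 0.038), Hbegf (0.98 ± 0.048), Tgfb2 (0.93 ± 0.053) and the intercalated disc gene Xirp1 (1.21 ± 0.070). Cytoskeletal genes and targets of serum response factor (SRF) formed 1 list, the cytoskeleton and SRF genes. This list also rose: 18 of 29 rose and 2 fell, or 18 and 3 adjusted over the list alone (adjusted p = 4.8e-06, and adjusted p = 0.0521 with an estimated correlation). The tubulin gene Tubb6 rose by 1.14 ± 0.047 and Srf itself by 0.67 ± 0.043.

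Genes of fatty acid oxidation fell at 6 h of PE: 23 of 29 fell and 2 rose, or 23 and 3 adjusted over the list alone (adjusted p = 7.0e-09, and adjusted p = 0.0521 with an estimated correlation). Hadh changed by -0.66 ± 0.045, Cpt2 by -0.67 ± 0.049, and Pdk4, which restrains glucose oxidation, by -1.06 ± 0.087. In the respiratory chain list, 15 of 30 fell and 3 rose, or 16 and 3 adjusted over the list alone (adjusted p = 0.00253, and adjusted p = 0.222 with an estimated correlation), with a median of -0.10. Of genes known to be lowered in hypertrophy, 12 of 18 fell and 2 rose (adjusted p = 0.00445, and adjusted p = 0.0745 with an estimated correlation). The potassium channel gene Kcnj11 fell (-1.29 ± 0.062), while the glucose transporter gene Slc2a4 rose (0.55 ± 0.061). Heat shock genes (8 of 16 rose and 1 fell; adjusted p = 0.00305, and adjusted p = 0.266 with an estimated correlation) rose with Hspa1a at 1.44 ± 0.069. Inflammatory genes (13 of 26 rose and 2 fell; adjusted p = 0.00375, and adjusted p = 0.231 with an estimated correlation) rose. Il6, dim before PE, was at 1.97 ± 0.15 and Ccl7 at 0.88 ± 0.079, while the chemokine gene Cxcl12 fell (-0.57 ± 0.047). Smooth muscle and pericyte markers also moved: 9 of 14 rose and 3 fell, or 10 and 3 adjusted over the list alone (adjusted p = 0.00305, and adjusted p = 0.0521 with an estimated correlation). Cspg4 was at 1.63 ± 0.077 and Acta2 at 0.85 ± 0.061. Of interferon response genes, 8 of 27 fell and 1 rose, or 7 and 1 adjusted over the list alone (adjusted p = 0.0348, and adjusted p = 0.619 with an estimated correlation). Irf1 changed by -0.55 ± 0.044. That call ended without replicate 3 of the unstimulated arrays (adjusted p = 0.138), without replicate 1 of the DMSO with PE arrays (adjusted p = 0.104), on repeating quantile normalization (adjusted p = 0.0542) and without dim genes (adjusted p = 0.120). In all, 4908 genes passed the threshold at 6 h of PE, 2416 raised and 2492 lowered, of which 133 and 70 changed at least 2-fold.

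After 48 h of PE, genes of cell division and the hypertrophic programme stood higher than in the 90 min cells. All 35 measured cell cycle and mitosis genes rose, with a median of 1.01 (adjusted p = 7.8e-24, and adjusted p = 0.00196 with an estimated correlation). The cyclin gene Ccnb1 rose 3.40-fold (1.76 ± 0.059), Top2a 2.94-fold (1.56 ± 0.060), and the spindle genes Prc1 and Kif20a by 1.50 ± 0.040 and 1.47 ± 0.048. Of hypertrophic marker genes, 17 of 19 rose and 0 fell, with a median of 0.69 (adjusted p = 7.0e-11, and adjusted p = 0.0376 with an estimated correlation). Hbegf, a growth factor of the EGF family, rose 2.79-fold (1.48 ± 0.043), Fhl1 2.13-fold (1.09 ± 0.034), and the fetal genes Acta1 and Nppa by 0.78 ± 0.030 and 0.78 ± 0.033. Of genes known to be lowered in hypertrophy, 13 of 18 fell and 2 rose (adjusted p = 1.7e-04, and adjusted p = 0.0403 with an estimated correlation). Among them were myoglobin, Mb (-1.27 ± 0.061), Kcnj11 (-0.96 ± 0.056), Abcc9 (-1.02 ± 0.062) and Atp2a2, which encodes the calcium pump of the sarcoplasmic reticulum (-0.47 ± 0.033, and -1.04 on a less bright probe set).

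The largest single rises at 48 h of PE were Esm1, a proteoglycan (2.62 ± 0.15), Wfdc1 (2.43 ± 0.048), the matrix protease Mmp3 (2.39 ± 0.18), the chemokine Ccl27 (2.17 ± 0.093) and the BMP antagonist Grem1 (2.12 ± 0.071), together with Hsf2bp (2.30 ± 0.13). The largest falls were Reg3b, a secreted lectin (-2.65 ± 0.081), the aldolase gene Aldoc (-2.52 ± 0.051), Dhrs7c (-2.37 ± 0.12), the imprinted gene Mest (-2.06 ± 0.063), the potassium channel subunit gene Kcnip2 (-2.04 ± 0.18) and Pik3ip1 (-1.96 ± 0.070). Each had an adjusted p of at most 1.6e-06. Esm1, Mmp3 and Hsf2bp were dim before PE and Kcnip2 after it, and a dimmer probe set of Pik3ip1 did not change (0.04, adjusted p = 0.684). In total 5809 genes passed the threshold, 2824 raised and 2985 lowered, with 185 and 88 changed at least 2-fold.

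Metabolic, stress and other lists also passed at 48 h of PE, some raised and some lowered. Cholesterol synthesis rose (15 of 18 rose and 0 fell; adjusted p = 1.5e-04, and adjusted p = 0.105 with an estimated correlation), with Idi1 at 0.53 ± 0.035 and Fdps at 0.46 ± 0.042. Heat shock genes rose (11 of 16 rose and 1 fell; adjusted p = 2.1e-04, and adjusted p = 0.137 with an estimated correlation). Cytoskeleton and SRF genes rose too (18 of 29 rose and 2 fell, or 19 and 3 adjusted over the list alone; adjusted p = 2.3e-05, and adjusted p = 0.0711 with an estimated correlation). The smooth muscle calponin gene Cnn1 rose by 1.59 ± 0.058. Fatty acid oxidation fell (17 of 29 fell and 2 rose; adjusted p = 6.6e-04, and adjusted p = 0.189 with an estimated correlation). Hadh changed by -1.11 ± 0.040 and Acaa2 by -0.72 ± 0.041, and the uncoupling protein gene Ucp2 rose (0.60 ± 0.051). Unfolded protein response genes fell (15 of 25 fell and 3 rose, or 16 and 3 adjusted over the list alone; adjusted p = 6.9e-04, and adjusted p = 0.0711 with an estimated correlation). Trib3 was at -0.72 ± 0.047 and Herpud1 at -0.64 ± 0.043. Of the list of BET proteins and transcription elongation factors, 13 of 25 fell and 4 rose, or 14 and 4 adjusted over the list alone (adjusted p = 0.00980, and adjusted p = 0.245 with an estimated correlation). Mllt3 fell (-1.06 ± 0.076) and Ell2 rose (0.45 ± 0.056). MYC and ribosome biogenesis remained higher as a list (15 of 28 rose and 2 fell, or 15 and 3 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.348 with an estimated correlation), and so did immediate early genes (15 of 28 rose and 5 fell; adjusted p = 0.0243, and adjusted p = 0.338 with an estimated correlation). Rrp12 was at 0.87 ± 0.064 and Fos at 0.86 ± 0.063.

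Contractile and channel genes were mixed at 48 h of PE. Of sarcomere genes, 11 of 22 rose and 5 fell (adjusted p = 0.0313, and adjusted p = 0.272 with an estimated correlation). Tcap was at 1.12 ± 0.036 and Myh7, the slow myosin heavy chain, at 0.50 ± 0.040 (1.14 on a less bright probe set), against Tnni1 at -0.51 ± 0.047. The sarcomere call ended on repeating quantile normalization (adjusted p = 0.180) and on averaging probe sets (adjusted p = 0.0616). Of calcium handling and channel genes, 14 of 26 fell and 4 rose (adjusted p = 0.0228, and adjusted p = 0.189 with an estimated correlation). The connexin gene Gja5 fell (-1.73 ± 0.069). Averaging probe sets also ended that call (adjusted p = 0.0616). Interferon response genes fell (11 of 27 fell and 0 rose; adjusted p = 0.00845, and adjusted p = 0.514 with an estimated correlation), with Irf1 at -0.43 ± 0.039. The list did not pass without replicate 3 of the DMSO with PE arrays at 48 h (adjusted p = 0.0501). Markers of other cell types moved in both directions. Smooth muscle and pericyte markers rose (9 of 14 rose and 2 fell; adjusted p = 0.00545, and adjusted p = 0.0717 with an estimated correlation). Fibroblast markers fell (8 of 16 fell and 3 rose, or 9 and 3 adjusted over the list alone; adjusted p = 0.0359, and adjusted p = 0.128 with an estimated correlation). Dpt changed by -0.88 ± 0.049 and Pdgfra by -0.73 ± 0.055, while Thy1 rose (1.45 ± 0.083). Macrophage and leukocyte markers fell (8 of 17 fell and 1 rose; adjusted p = 0.0313, and adjusted p = 0.113 with an estimated correlation), with Tyrobp at -0.65 ± 0.050, dim in both groups. Without dim genes neither of the last 2 lists passed (adjusted p = 0.0940 and 0.0608), and the leukocyte list did not pass without replicate 1 of DMSO with PE at 48 h (adjusted p = 0.0521).

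Late PE was compared with early PE, both in DMSO. Between 6 h and 48 h all 35 cell cycle genes rose, with a median of 1.04 (adjusted p = 5.0e-33, and adjusted p = 5.3e-04 with an estimated correlation). They included Kif20a (1.70 ± 0.054), Prc1 (1.28 ± 0.044) and Ccnb2 (1.40 ± 0.052). The spindle gene Spag5 (1.82 ± 0.10), the sodium channel subunit gene Scn3b (1.81 ± 0.055), RGD1559545 (1.74 ± 0.12) and Depdc1 (1.71 ± 0.096) had the largest rises. Reg3b (-2.76 ± 0.090), the hepcidin gene Hamp (-2.75 ± 0.074), Ch25h (-2.40 ± 0.11) and the thrombomodulin gene Thbd (-2.16 ± 0.075) had the largest falls. RGD1559545 was dim at 6 h and Ch25h at 48 h, and a dimmer probe set of Thbd did not pass (-0.08). Unfolded protein response genes fell (21 of 25 fell and 0 rose, or 23 and 0 adjusted over the list alone; adjusted p = 1.2e-09, and adjusted p = 0.00592 with an estimated correlation), with Chac1 at -1.05 ± 0.066. MYC and ribosome biogenesis fell (23 of 28 fell and 1 rose, or 24 and 1 adjusted over the list alone; adjusted p = 1.7e-08, and adjusted p = 0.126 with an estimated correlation). Immediate early genes fell too (20 of 28 fell and 2 rose; adjusted p = 2.1e-08, and adjusted p = 0.0846 with an estimated correlation). Nolc1 was at -0.54 ± 0.047, Nr4a3 at -1.94 ± 0.089 and Fos at -1.28 ± 0.071. Leukocyte markers fell (9 of 17 fell and 0 rose, or 11 and 0 adjusted over the list alone; adjusted p = 0.00401, and adjusted p = 0.0538 with an estimated correlation). BET and elongation factors fell (10 of 25 fell and 0 rose; adjusted p = 0.0189, and adjusted p = 0.314 with an estimated correlation), and so did inflammatory genes (8 of 26 fell and 1 rose; adjusted p = 0.0317, and adjusted p = 0.314 with an estimated correlation). Cholesterol synthesis rose (10 of 18 rose and 0 fell, or 11 and 0 adjusted over the list alone; adjusted p = 0.00728, and adjusted p = 0.269 with an estimated correlation). Ribosomal proteins fell (8 of 17 fell and 0 rose; adjusted p = 0.0264, and adjusted p = 0.380 with an estimated correlation). Sarcomere genes rose (9 of 22 rose and 3 fell, or 10 and 3 adjusted over the list alone; adjusted p = 0.0469, and adjusted p = 0.314 with an estimated correlation). Centring the arrays ended both calls (adjusted p = 0.0561 and 0.0660), and repeating quantile normalization ended that for the sarcomere (adjusted p = 0.194). The comparison called 4565 genes, 2144 raised and 2421 lowered.

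JQ1 at 6 h of PE changed 7156 genes, 3362 raised and 3794 lowered, with 163 and 490 changed at least 2-fold. The BET gene Brd2 rose 4.01-fold (2.00 ± 0.054), with the histone gene H3c1 (2.24 ± 0.13), the stress transcription factor Atf3 (2.20 ± 0.089), the hormone precursor Trh (2.19 ± 0.11), Arrdc2 (2.17 ± 0.072) and Pgbd5 (2.00 ± 0.14). The secreted phospholipase gene Pla2g5 fell 10.6-fold (-3.41 ± 0.068), the connexin gene Gja5 9.17-fold (-3.20 ± 0.078) and the stanniocalcin gene Stc1 8.66-fold (-3.11 ± 0.067). The cytokine subunit gene Il12a (-3.08 ± 0.14), Thbd (-3.05 ± 0.075) and Tmem196 (-2.89 ± 0.12) followed. Adjusted p was at most 9.0e-08 for these 12 genes. H3c1 and Pgbd5 were dim without JQ1 and Il12a with it, and dimmer probe sets of Gja5 (-0.28) and Thbd (-0.08) did not pass. Of the short list of histone genes and genes raised by BET inhibitors in other cells, 7 of 9 rose and 1 fell, or 7 and 2 adjusted over the list alone, with a median of 1.17 (adjusted p = 0.00696, and adjusted p = 0.224 with an estimated correlation). Hexim1, which sequesters the elongation kinase P-TEFb, rose 2.49-fold (1.31 ± 0.045) and Hist2h2be 2.85-fold (1.51 ± 0.072), whereas Zmynd8 fell (-1.62 ± 0.070).

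Interferon response genes fell furthest of the 32 lists under JQ1 at 6 h: 23 of 27 fell and 1 rose, with a median of -1.02 (adjusted p = 4.3e-05, and adjusted p = 0.354 with an estimated correlation). Rtp4 changed by -2.50 ± 0.17, Gbp2 by -1.43 ± 0.11, Irf9 by -1.14 ± 0.10 and Ifitm3 by -0.83 ± 0.059. Cholesterol synthesis fell (15 of 18 fell and 1 rose; adjusted p = 1.3e-04, and adjusted p = 0.176 with an estimated correlation). Msmo1 was at -0.84 ± 0.057, Fdft1 at -0.81 ± 0.056 and its regulator Srebf2 at -0.70 ± 0.049. In the respiratory chain, 22 of 30 fell and 0 rose, or 25 and 0 adjusted over the list alone (adjusted p = 1.1e-04, and adjusted p = 0.176 with an estimated correlation). Ndufs3 was at -0.62 ± 0.038 and Sdhd at -0.54 ± 0.034. Cell cycle genes fell (22 of 35 fell and 4 rose; adjusted p = 0.00284, and adjusted p = 0.182 with an estimated correlation), with Mcm6 at -0.82 ± 0.037 and Ube2c at -1.07 ± 0.067, while Pcna rose (0.41 ± 0.036). Calcium handling and channel genes fell (16 of 26 fell and 3 rose; adjusted p = 0.00420, and adjusted p = 0.176 with an estimated correlation). Genes known to be lowered in hypertrophy, which share 8 members with them, also fell (11 of 18 fell and 1 rose; adjusted p = 0.00395, and adjusted p = 0.176 with an estimated correlation). Kcnj11 changed by -2.78 ± 0.062, Kcnq1 by -0.92 ± 0.051 and the ryanodine receptor gene Ryr2 by -0.63 ± 0.043, with the exchanger gene Slc8a1 higher (0.62 ± 0.073).

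Some growth-related lists rose under JQ1 at 6 h. Of immediate early genes, 18 of 28 rose and 3 fell (adjusted p = 1.3e-04, and adjusted p = 0.182 with an estimated correlation), with Jun at 1.11 ± 0.056 and Klf2 at 1.06 ± 0.054. Of MYC and ribosome biogenesis genes, 19 of 28 rose and 2 fell (adjusted p = 1.3e-04, and adjusted p = 0.224 with an estimated correlation), with Myc itself up 2.58-fold (1.37 ± 0.087) and Odc1 at 0.63 ± 0.043. Heat shock genes rose (11 of 16 rose and 3 fell; adjusted p = 0.00481, and adjusted p = 0.224 with an estimated correlation), as did cytoskeleton and SRF genes (21 of 29 rose and 7 fell; adjusted p = 0.00953, and adjusted p = 0.224 with an estimated correlation). Hspa1a was at 1.27 ± 0.069 and Lmod2 at 0.74 ± 0.036. Fibroblast markers fell (10 of 16 fell and 0 rose, or 11 and 1 adjusted over the list alone; adjusted p = 0.00305, and adjusted p = 0.176 with an estimated correlation). Pdgfra changed by -1.86 ± 0.062 and Ddr2 by -1.09 ± 0.057. Smooth muscle and pericyte markers fell (10 of 14 fell and 3 rose; adjusted p = 0.0229, and adjusted p = 0.176 with an estimated correlation), with Cspg4 at -1.16 ± 0.077. Without dim genes the smooth muscle list no longer passed (adjusted p = 0.0595). Centring each array on its median moved the raised share of calls from 47.0% to 60.1%, so the balance over all calls depended on scaling. Centring added only 0.085 to every gene. Among changes of at least 2-fold before centring, 163 genes rose and 490 fell.

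By 48 h, JQ1 held cell division, matrix and interferon genes far below the level of DMSO with PE. Of cell cycle and mitosis genes, 34 of 35 fell and 0 rose, with a median of -1.58 (adjusted p = 1.2e-16, and adjusted p = 0.00382 with an estimated correlation). Ccnb1 fell 7.60-fold (-2.93 ± 0.059), with Prc1 at -2.34 ± 0.040, Kif20a at -2.39 ± 0.048 and Mcm6 at -1.56 ± 0.033. Of interferon response genes, 26 of 27 fell and 1 rose, with a median of -2.06 (adjusted p = 8.0e-10, and adjusted p = 0.165 with an estimated correlation). Rtp4 (-3.66 ± 0.15) and Gbp2 (-2.17 ± 0.095) were among them, and Irf1 was higher (0.19 ± 0.039). Of matrix and TGF-beta response genes, 26 of 31 fell and 3 rose (adjusted p = 6.2e-08, and adjusted p = 0.00557 with an estimated correlation). Tenascin C, Tnc, fell 7.52-fold (-2.91 ± 0.066), with the collagen crosslinking enzyme Lox at -2.05 ± 0.065 and Tgfb2 at -1.56 ± 0.048, against the protease inhibitor Timp1 at 0.27 ± 0.044. All 16 fibroblast markers, 5 of them also on the matrix list, fell with these genes, with a median of -1.16 (adjusted p = 7.8e-09, and adjusted p = 0.00365 with an estimated correlation). Periostin, Postn, changed by -1.79 ± 0.035, Dpt by -2.13 ± 0.049, Mfap5 by -2.89 ± 0.077 and Dcn by -1.45 ± 0.042. Smooth muscle and pericyte markers fell as well (11 of 14 fell and 1 rose; adjusted p = 4.8e-04, and adjusted p = 0.0317 with an estimated correlation). Cnn1 fell (-2.02 ± 0.058) and the muscle gene Des rose (0.28 ± 0.035). Cardiomyocyte markers went both ways (6 of 15 rose and 8 fell; adjusted p = 0.253), with the troponin gene Tnni3 at -1.55 ± 0.036 and Mybpc3 at 0.65 ± 0.035.

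Secreted factors and the hypertrophic programme were also lower with JQ1 at 48 h, beside the fall of fibroblast markers (median -1.16). Of growth factors and neurohormones, 23 of 27 fell and 0 rose (adjusted p = 1.8e-07, and adjusted p = 0.00468 with an estimated correlation). They included Igf1 (-1.67 ± 0.040), Bmp2 (-1.66 ± 0.048), Vegfc (-0.97 ± 0.044) and Nppb, the B-type natriuretic peptide (-0.90 ± 0.041). Of hypertrophic marker genes, 15 of 19 fell and 1 rose (adjusted p = 3.4e-05, and adjusted p = 0.0958 with an estimated correlation). Adamts1 was at -1.97 ± 0.067 and the calcineurin regulator Rcan1 at -1.13 ± 0.051. That list shares 6 genes with the growth factor list. Inflammatory genes fell (18 of 26 fell and 1 rose, or 18 and 2 adjusted over the list alone; adjusted p = 4.9e-05, and adjusted p = 0.0937 with an estimated correlation). Il6 fell to a dim level (-3.22 ± 0.14), with Ccl7 at -2.87 ± 0.071 and Ccl2 at -2.09 ± 0.039. All 18 cholesterol synthesis genes fell (adjusted p = 3.2e-07, and adjusted p = 0.0372 with an estimated correlation), with Msmo1 at -1.10 ± 0.051 and Fdps at -0.81 ± 0.042. The respiratory chain fell (20 of 30 fell and 3 rose; adjusted p = 1.0e-03, and adjusted p = 0.136 with an estimated correlation). The unfolded protein response fell (16 of 25 fell and 3 rose, or 17 and 3 adjusted over the list alone; adjusted p = 0.00852, and adjusted p = 0.112 with an estimated correlation), and cytoskeleton and SRF genes fell (17 of 29 fell and 6 rose, or 17 and 7 adjusted over the list alone; adjusted p = 0.0110, and adjusted p = 0.174 with an estimated correlation). Cox7a1 was at -1.11 ± 0.064, Xbp1 at -0.77 ± 0.035 and Myl9 at -1.44 ± 0.044. Genes known to be lowered in hypertrophy were lower still (10 of 18 fell and 5 rose; adjusted p = 0.0381, and adjusted p = 0.140 with an estimated correlation). The mitochondrial creatine kinase gene Ckmt2 was at -2.56 ± 0.073 and Mb at -1.51 ± 0.061. The list's call ended on averaging probe sets (adjusted p = 0.0587).

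Fewer groups rose under JQ1 at 48 h. The histone and BET inhibitor list rose (8 of 9 rose and 1 fell; adjusted p = 1.0e-03, and adjusted p = 0.112 with an estimated correlation). Hexim1 was up 3.09-fold (1.63 ± 0.040) and H2aj at 0.98 ± 0.045. Of BET proteins and elongation factors, 15 of 25 rose and 4 fell (adjusted p = 0.00542, and adjusted p = 0.174 with an estimated correlation). Brd2 rose 4.50-fold (2.17 ± 0.048), the RNA polymerase subunit gene Polr2a by 1.38 ± 0.050 and Mllt3 by 1.41 ± 0.076, while Hexim2 fell (-0.82 ± 0.052). Muscle atrophy genes rose (13 of 20 rose and 4 fell; adjusted p = 0.0247, and adjusted p = 0.130 with an estimated correlation). Bnip3l was at 1.01 ± 0.042 and the ubiquitin ligase gene Trim63 at 0.46 ± 0.035, but Trim54 fell (-3.20 ± 0.063). Centring the arrays ended the call (adjusted p = 0.0569). Nudt6 (2.45 ± 0.074), Fscn2 (2.12 ± 0.12), Atp6v1c2 (2.02 ± 0.091), Flrt3 (1.94 ± 0.095) and Mturn (1.93 ± 0.089) joined Brd2 as the largest rises. The largest falls were asporin, Aspn, a matrix proteoglycan (-5.33 ± 0.11), Grem1 (-4.59 ± 0.071), Glod5 (-4.55 ± 0.092), Wfdc1 (-4.52 ± 0.048), the M-band gene Myom2 (-4.44 ± 0.084) and Pla2g5 (-4.28 ± 0.061). Adjusted p was at most 8.5e-09 for these 12 genes. Aspn, Glod5 (mean 5.18) and Grem1 (mean 5.78) were dim with JQ1, and another probe set of Aspn gave -4.04. Fscn2, Atp6v1c2 and Flrt3 were dim without JQ1. In total 7858 genes passed, 3957 raised and 3901 lowered, with 185 and 796 changed at least 2-fold. Centring moved the raised share of calls from 50.4% to 62.3%.

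**Figure D1:**
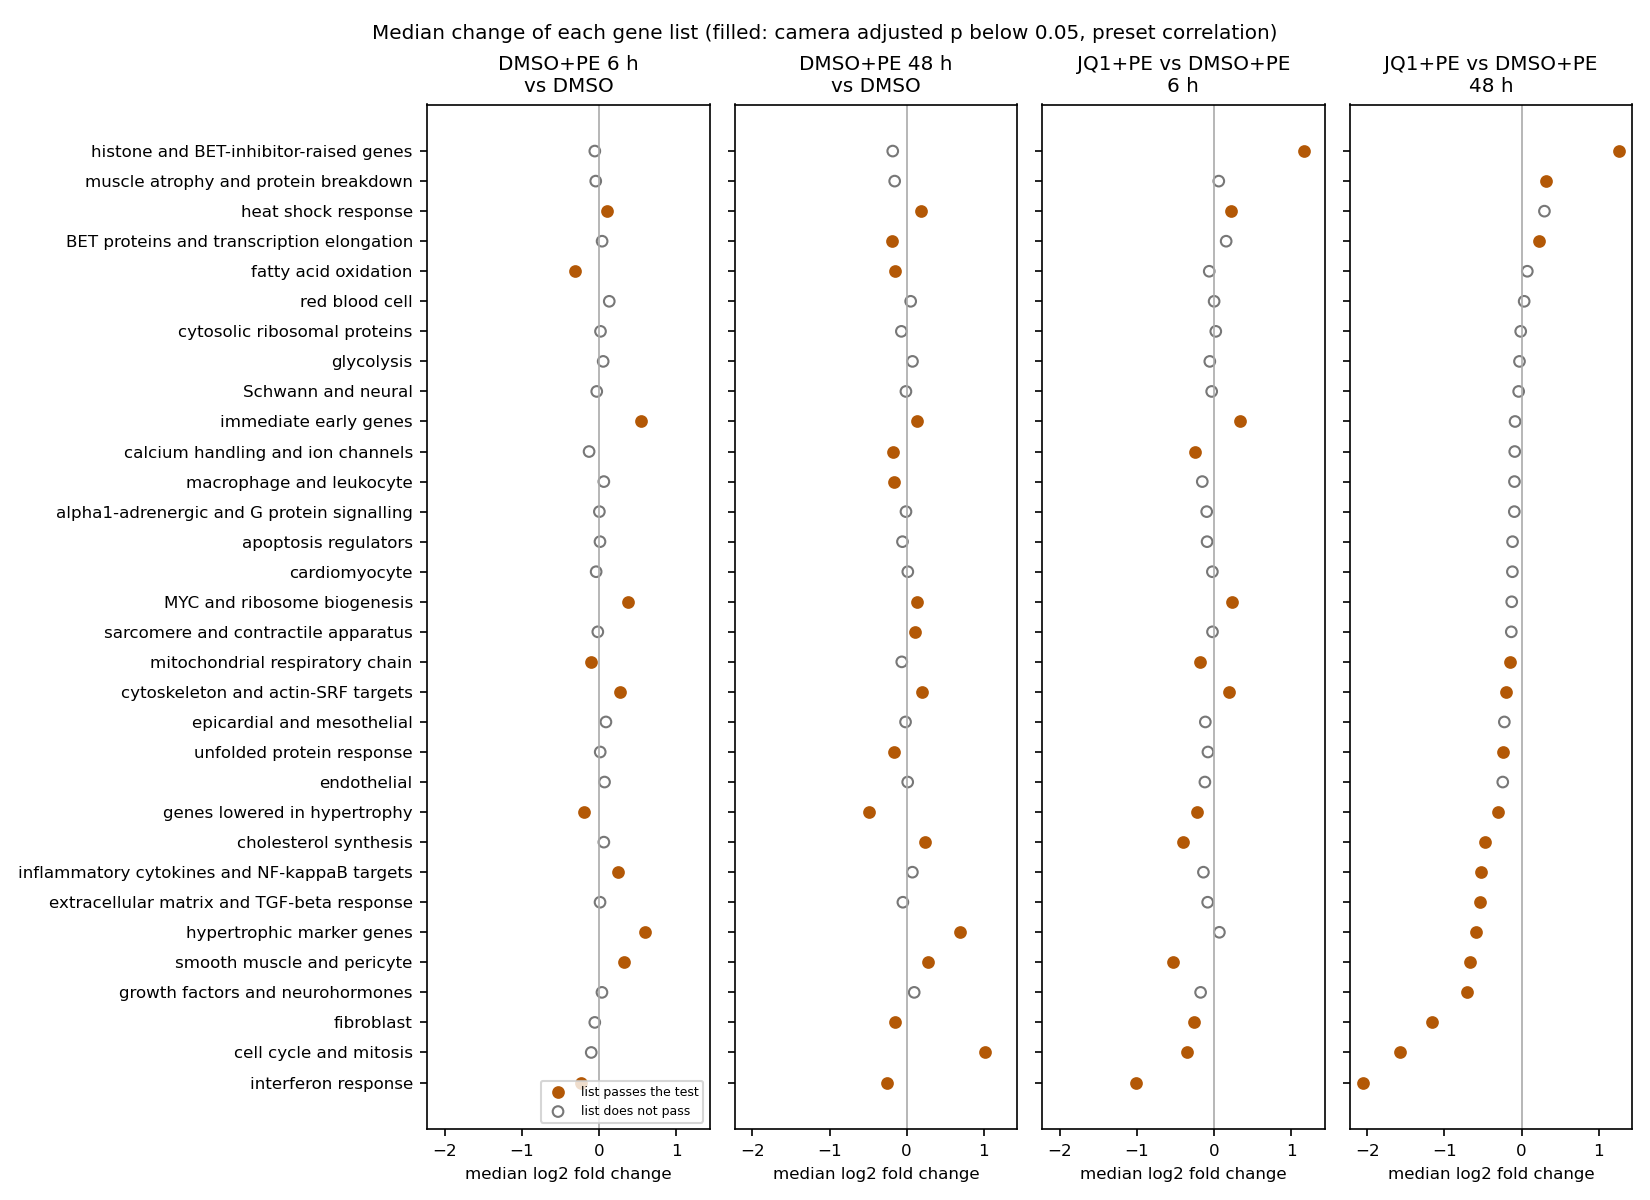
Median log2 fold change (horizontal axes) of each of the 32 gene lists in 4 comparisons, with filled points for lists that passed camera with the preset correlation and open points for the rest. Interferon response and cell cycle genes lie lowest under JQ1 at 48 h, at -2.06 and -1.58, and cell cycle genes lie highest after 48 h of PE, at 1.01.

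Several panel genes lay near the top of the arrays' range, where differences can be compressed. The means of Nppa, Nppb, Acta1, Myh6, Myh7, Atp2a2 and Ccn2 over the arrays ran from 13.72 to 14.27, close to the highest value in the table, so the sizes of their changes are not compared. PE raised Nppb at 6 h (0.67 ± 0.046) and 48 h (0.90 ± 0.041). JQ1 left Nppb without a called difference at 6 h (0.07 ± 0.046, adjusted p = 0.229, and 0.15 after centring, adjusted p = 0.0176) and lowered it at 48 h (-0.90 ± 0.041). Nppb with JQ1 and PE at 48 h then differed from unstimulated cells by 0.00 ± 0.041 (adjusted p = 0.959). In that comparison Nppa (0.60 ± 0.033), Acta1 (0.80 ± 0.030) and Myh7 (0.11 ± 0.040, adjusted p = 0.0260) were still higher. Myh6 (-0.25 ± 0.032), Atp2a2 (-0.35 ± 0.033) and Ccn2 (-0.35 ± 0.039) were lower. Nppa rose with PE (0.34 ± 0.037 and 0.78 ± 0.033) and was lower with JQ1 at 48 h (-0.19 ± 0.033, adjusted p = 2.4e-04). Acta1, also raised by PE (0.56 ± 0.033 at 6 h), was higher with JQ1 at 6 h (0.51 ± 0.033) and not called at 48 h (0.02 ± 0.030, adjusted p = 0.591; 0.11 after centring, adjusted p = 0.0085). Myh7 was lower with JQ1 at both times (-0.46 ± 0.045 and -0.39 ± 0.040, and -0.65 and -0.63 on the less bright probe set). Myh6, the fast myosin heavy chain, was lower after 48 h of PE (-0.25 ± 0.032, and -1.05 on a less bright probe set). Its JQ1 differences of 0.04 at 6 h and 0.00 at 48 h did not pass, except on averaging probe sets at 48 h (0.23, adjusted p = 0.0091) and after centring at 6 h (0.12, adjusted p = 0.0303).

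Among the other panel genes, Il6, dim before PE, was higher with PE (1.50 ± 0.14 at 48 h) and lower with JQ1 at 6 h (-1.47 ± 0.15) and 48 h. Rcan1 rose with PE (0.94 ± 0.057 at 6 h, 0.57 ± 0.051 at 48 h). The fall of Rcan1 with JQ1 at 6 h (-0.21 ± 0.057) did not pass without replicate 1 of DMSO with PE at 6 h (-0.16, adjusted p = 0.0786) or after centring (-0.13, adjusted p = 0.0902), and it was -1.13 ± 0.051 at 48 h. Ccn2, a matricellular growth factor, rose with 48 h of PE (0.24 ± 0.039) and was lower with JQ1 at 48 h (-0.59 ± 0.039). Clcf1, a cytokine of the IL-6 family, rose with PE (0.62 ± 0.10 and 0.46 ± 0.090) and was lower with JQ1 at 48 h (-0.60 ± 0.090). The rise of Clcf1 with JQ1 at 6 h (0.27 ± 0.10, adjusted p = 0.0387) did not pass without replicate 3 of JQ1 with PE at 6 h (0.17, adjusted p = 0.141). The call also ended with the groups compared alone (adjusted p = 0.123), with array weights (adjusted p = 0.0918) and with the replicate block (adjusted p = 0.0816). Clcf1 was dim in every group (means 3.37 to 4.41), so these differences lie near background. Myc rose with 6 h of PE (0.63 ± 0.087) and not at 48 h (-0.11 ± 0.078, adjusted p = 0.275). It was lower with JQ1 at 48 h (-0.25 ± 0.078, adjusted p = 0.0146), a call that ended without replicate 2 of JQ1 with PE at 48 h (adjusted p = 0.0642) and after centring (adjusted p = 0.0864). For Atp2a2 the probe sets disagreed: JQ1 at 6 h gave -0.13 ± 0.037 on the brightest and 0.24 as the mean of its probe sets (adjusted p = 0.0018). The former did not pass without replicate 2 of DMSO with PE at 6 h (-0.10, adjusted p = 0.0968), with the groups compared alone (adjusted p = 0.0825) or after centring (-0.04, adjusted p = 0.408).

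**Figure D2:**
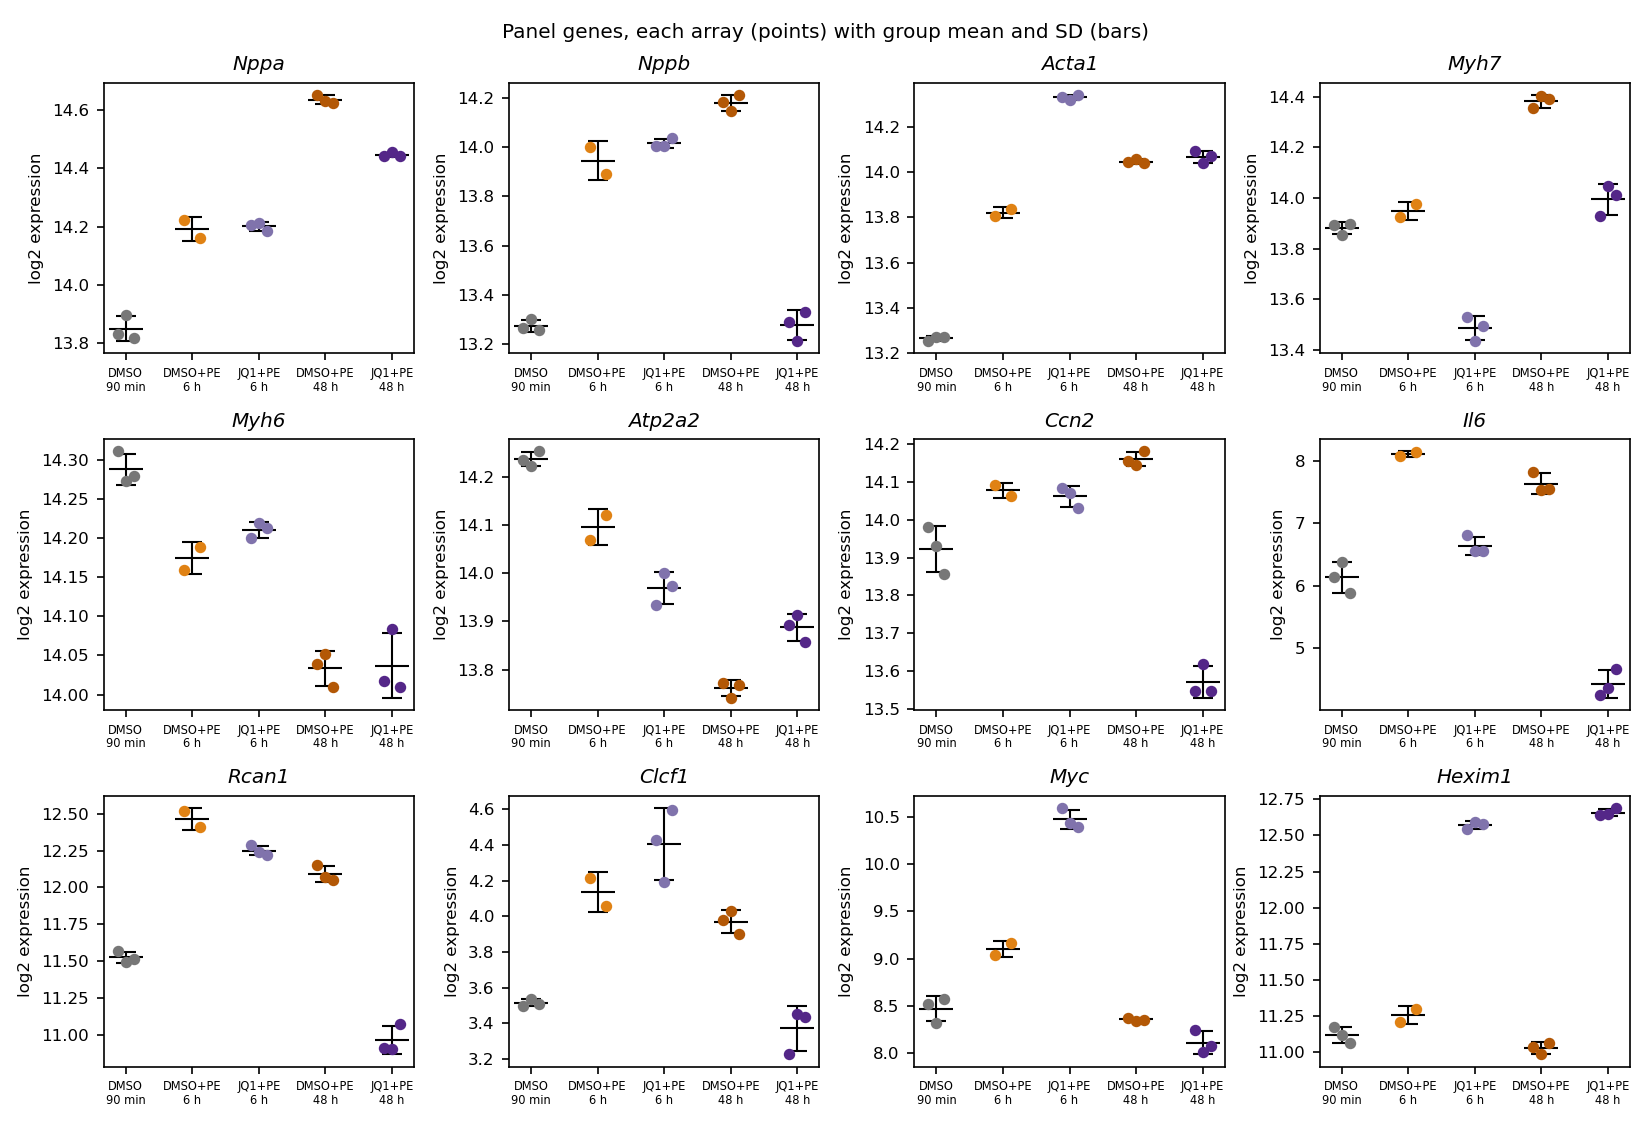
Log2 expression (vertical axes) of 12 panel genes on each of the 14 arrays by group, with points for arrays and bars for the group mean and SD. With JQ1 at 48 h, Nppb arrays lie at the level of unstimulated DMSO arrays (difference 0.00), while those of Nppa (0.60) and Acta1 (0.80) lie higher. Hexim1 arrays lie higher in both JQ1 groups.

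Whether JQ1 acted differently at the 2 times was tested as the difference of its effects, 48 h minus 6 h. It passed for 5111 genes, 2695 with a higher and 2416 with a lower value at 48 h. G0s2, an inhibitor of triglyceride lipolysis, had a difference of 3.22 ± 0.089, moving from -2.29 ± 0.066 at 6 h to 0.93 ± 0.059 at 48 h. Lrrc10 (2.69 ± 0.095), Stc1 (2.52 ± 0.089) and the mitochondrial coactivator gene Ppargc1a (2.51 ± 0.36) followed. Aspn (-4.63 ± 0.17), Myom2 (-3.50 ± 0.13), Glod5 (-3.38 ± 0.14) and Fndc1 (-2.87 ± 0.10) had the largest negative differences. Ppargc1a was dim with JQ1 at 6 h, and Aspn and Glod5 with JQ1 at 48 h. Across genes, which are not independent replicates, JQ1 effects at 6 h and 48 h correlated at r = 0.697 (rho = 0.650) with no arrays in common, and unchanged groups gave a mean r of 0.00043. Of 3362 genes raised at 6 h, 2312 were raised at 48 h, against 1009 for independent lists, and 266 were lowered. Of 3794 lowered at 6 h, 2630 were lowered at 48 h, against 1123, and 372 were raised.

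**Figure D3:**
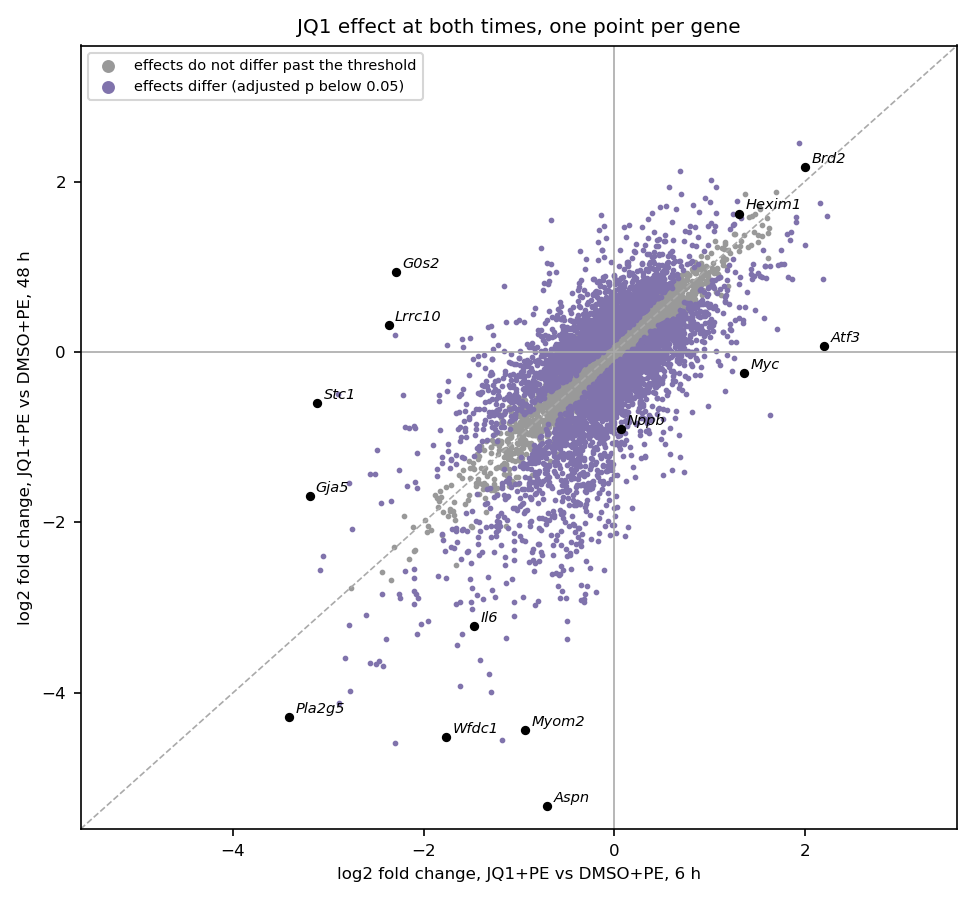
JQ1 effect at 48 h (vertical axis, log2 fold change) against 6 h (horizontal axis), with 1 point per gene, coloured where the difference of effects passed the threshold, and a dashed line of equality. The effects correlate across genes (r = 0.697), with G0s2, Lrrc10, Atf3 and Aspn far from the line.

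The design asks whether JQ1 opposed the PE response. No group received JQ1 without PE, so a change opposite to PE cannot be told from a JQ1 effect that would occur without PE. The PE groups also differ from the unstimulated cells in time in culture, so sets raised or lowered by PE may hold both. At 48 h, of 2824 genes raised by PE, 1557 (55.1%) were lowered by JQ1, against 836 for independent lists of these sizes. Of 2985 genes lowered by PE, 1530 were raised by JQ1, against 896. At 6 h the counts were 877 of 2416 (36.3%), against 695, and 700 of 2492, against 635. Genes moved the same way by both at 6 h numbered 893 raised, against 616, and 1110 lowered, against 717. At 48 h they numbered 582 raised, against 848, and 838 lowered, against 883. The difference between the times was not tested. At each time both comparisons use the same DMSO with PE arrays, which alone pushes them apart. Part of the excess of opposite changes may therefore come from sharing, at 6 h as at 48 h. For 48 h the correlation across genes was r = -0.332 (rho = -0.284; -0.499 in unchanged groups), and the covariance of -0.0621, less -0.0027 from sharing, left -0.0595. For 6 h, r was 0.0762 (rho = 0.0491, and -0.601 in unchanged groups), and the covariance of 0.0109, less -0.0040 from sharing, gave 0.0149.

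Sets of PE genes were also tested in the JQ1 comparison of the other time, which shares no arrays with them. Genes raised by PE at 6 h had a median JQ1 effect of -0.09 at 48 h (1114 of 2416 lowered, 670 raised; camera p = 5.5e-04, adjusted p = 0.0022 over 4 sets, and p = 0.166 with an estimated correlation). Genes lowered by PE at 6 h had a median of 0.10 (1205 of 2492 raised, 803 lowered, mean 0.0049; camera p = 0.0160, adjusted p = 0.0320, and p = 0.419 with an estimated correlation). Centring, which adds the same amount to every gene, moved these medians to -0.0014 and 0.19, so their distance from 0 depended on scaling. In the reverse direction, genes raised by PE at 48 h had a median JQ1 effect at 6 h of -0.02 (adjusted p = 0.733) and genes lowered had -0.07 (adjusted p = 0.101). For sets limited to 2-fold changes, p-values were adjusted over 4 sets as well. The 133 genes raised at least 2-fold by PE at 6 h had a median JQ1 effect of -0.67 at 48 h, with 95 lowered (adjusted p = 7.1e-13, and adjusted p = 0.0516 with an estimated correlation). The 70 genes lowered at least 2-fold then had 0.02, with 31 raised and 25 lowered (adjusted p = 0.464). Genes raised (185) and lowered (88) at least 2-fold by PE at 48 h both had negative medians under JQ1 at 6 h, -0.34 and -0.60 (adjusted p = 3.8e-05 and 1.8e-10, and adjusted p = 0.0516 for both with an estimated correlation).

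Against unstimulated cells, those given both JQ1 and PE differed in 8256 genes at 6 h (4071 raised) and 8017 at 48 h (4171 raised). Centring moved the raised share from 49.3% to 61.2% and from 52.0% to 65.5%, and shifted the median of all genes at 48 h by 0.10. At 6 h, MYC and ribosome biogenesis genes rose (28 of 28 rose and 0 fell; adjusted p = 2.3e-10, and adjusted p = 0.0783 with an estimated correlation). Hypertrophic markers rose as well (15 of 19 rose and 4 fell; adjusted p = 1.6e-04, and adjusted p = 0.107 with an estimated correlation). Interferon response genes fell (26 of 27 fell and 0 rose; adjusted p = 4.0e-07, and adjusted p = 0.319 with an estimated correlation). At 48 h all 27 interferon response genes lay lower (adjusted p = 1.9e-12, and adjusted p = 0.120 with an estimated correlation). Cell cycle genes fell (27 of 35 fell and 3 rose, or 28 and 4 adjusted over the list alone; adjusted p = 1.5e-06, and adjusted p = 0.0397 with an estimated correlation), and fibroblast markers fell (14 of 16 fell and 1 rose; adjusted p = 8.5e-08, and adjusted p = 0.00547 with an estimated correlation). Genes known to be lowered in hypertrophy lay below unstimulated levels (13 of 18 fell and 1 rose; adjusted p = 3.1e-05, and adjusted p = 0.0240 with an estimated correlation).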

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

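The tests weighed here for fibroblast markers, cell cycle genes and interferon response genes were chosen after the results were seen, while the counts of other sample splits were planned. The effect of JQ1 differed between 48 h and 6 h by a test of the difference itself for 10 panel genes. Values at 48 h minus 6 h were -0.20 for Nppa, -0.97 for Nppb, -0.49 for Acta1, 0.25 for Atp2a2, -0.57 for Ccn2, -1.75 for Il6, -0.91 for Rcan1, -0.87 for Clcf1, -1.62 for Myc and 0.31 for Hexim1. Nppa, Nppb, Acta1, Atp2a2 and Ccn2 lie near the top of the arrays' range, so the sizes of their differences are uncertain. The same holds for Il6, dim with JQ1 at 48 h, and for Clcf1, dim in every group. The Atp2a2 difference had the opposite sign on another of its probe sets (-0.20, adjusted p = 0.0203). The same test singled out G0s2 (3.22), Lrrc10 (2.69), Stc1 (2.52), Ppargc1a (2.51), Aspn (-4.63), Myom2 (-3.50), Glod5 (-3.38) and Fndc1 (-2.87).

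For 16 of the 32 lists the JQ1 effect differed between the times. Median differences below 0 were found for cell cycle genes (-1.29), interferon response (-0.85), fibroblast markers (-0.79), hypertrophic markers (-0.66), matrix and TGF-beta response (-0.45), immediate early genes (-0.42), cytoskeleton and SRF genes (-0.39), MYC and ribosome biogenesis (-0.33), and inflammatory genes (-0.28). The same held for growth factors (-0.27), smooth muscle and pericyte markers (-0.27) and the unfolded protein response (-0.14). Medians above 0 were found for calcium handling and channels (0.24), fatty acid oxidation (0.21), muscle atrophy genes (0.13) and BET and elongation factors (0.11). With an estimated correlation 6 calls held: cell cycle (adjusted p = 0.00227), hypertrophic markers (0.0244), cytoskeleton and SRF genes (0.0171), matrix (0.00531), fibroblast markers (0.00531) and growth factors (0.0244). The calcium handling call ended without replicate 1 of DMSO with PE at 6 h (adjusted p = 0.0545) and on averaging probe sets (adjusted p = 0.145), and the smooth muscle call without dim genes (adjusted p = 0.0874).

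A signal also appeared in the 1707 probe sets without a single gene symbol, which no gene comparison used. JQ1 raised 526 and lowered 306 of them at 48 h, with a largest rise of 3.41 and a largest fall of -3.74, and PE raised 268 and lowered 328 at 48 h. Calls were no more frequent than among the 13184 genes, of which 59.6% passed for JQ1 and 44.1% for PE at 48 h. Of changes of at least 2-fold in these probe sets, JQ1 raised 28 and lowered 44, and PE raised 12 and lowered 8.

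Fibroblast markers fell under JQ1 at 48 h, and cells from such preparations may hold residual fibroblasts despite pre-plating. Abundant markers away from the top of the arrays' range fell by different amounts, Col1a1 changing by -0.85 ± 0.041 and Dcn by -1.45 ± 0.042. A lower share of fibroblasts as the whole cause need not lower every marker by 1 amount. Markers near the dim limit (Fap, mean 6.52) or the top of the range (Col1a2, mean 13.56) can be compressed, and other cells may express some. For 14 of the 16 the 95% interval, from a spread that may be technical, excluded the list's median, which cannot decide the question. Centring added about 0.088 to every gene, so by construction it left the list's median at -1.07. An offset of that size between the arrays is small beside the fall. Repeating quantile normalization gave a median of -1.11. A lower share of fibroblasts, a change in what fibroblasts or myocytes express under JQ1, or both, stay open.

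Cell cycle genes rose with 48 h of PE in a culture prepared to hold mainly heart muscle cells, and residual dividing fibroblasts could contribute. Which cells carried the rise was not measured. A higher share of fibroblasts as the whole cause would raise their markers by about as much, but these went both ways (8 of 16 fell and 3 rose, Thy1 by 1.45 ± 0.083). Their median of -0.15 lay 1.16 below that of the cell cycle genes (permutation test, two-sided p = 1.0e-05, the smallest it can give; Benjamini-Hochberg p = 2.0e-05 over 2 tests). Smooth muscle and pericyte markers rose (median 0.28, adjusted p = 0.0717 with an estimated correlation), by 0.73 less than the cell cycle genes (permutation p = 4.3e-04, Benjamini-Hochberg p = 4.3e-04), so a part played by such cells, or by division of fibroblasts without a higher share, stays open. Both permutation tests shuffle genes as if they were independent, so their p-values do not measure the spread between arrays. Time in culture and PE cannot be told apart, because 0 arrays without PE at 48 h were used here, and an effect of PE stays open.

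Interferon response genes fell under JQ1 at 6 h and further at 48 h, but with an estimated correlation neither fall (adjusted p = 0.354 and 0.165) nor their difference (adjusted p = 0.279) passed. A lower share of leukocytes would take their markers down with the list, but the 5 leukocyte markers above the dim limit had a median 1.64 higher than the interferon genes at 48 h (exact permutation test, two-sided p = 0.0504, Benjamini-Hochberg p = 0.0504 over 2 tests). Cd14 (-1.24 ± 0.078), Lyz2 (-0.86 ± 0.081) and Fcer1g (-0.42 ± 0.053) fell, while Cd68 (-0.00 ± 0.061) and Laptm5 (0.06 ± 0.074) did not pass, and with 5 markers the 2 cannot be told apart. At 6 h the 16 fibroblast markers had a median 0.76 higher than the interferon genes (permutation test, two-sided p = 0.0030, Benjamini-Hochberg p = 0.0061). Both permutation tests shuffle genes as if they were independent, which genes of 1 list are not. Their p-values do not measure the spread between arrays, so they do not decide on fibroblast loss. Fibroblast loss and an effect of JQ1 on interferon genes within the cells, which the design allows, stay open.

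Other splits of the arrays were counted for the comparisons of 3 against 3. For PE at 48 h, JQ1 at 48 h, and JQ1 with PE against unstimulated cells at 6 h and 48 h, the real split gave 5809, 7858, 8256 and 8017 genes, and the highest of the other splits gave 0. In each, 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. The 1557 genes raised by PE and lowered by JQ1 at 48 h were reached by 2 of 100 splits of 9 arrays, the real one included. The count can be high whenever arrays of 1 group hold the shared place, so the splits cannot decide whether JQ1 opposed PE. The other was higher, at 2641, and kept 1 group whole: it set the 3 JQ1 arrays in the middle place between mixtures of the other groups, so it followed the JQ1 effect itself. The next highest split shared 0 genes.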

How the results depend on the processing

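Of the alternatives, testing the gene lists under both rescalings was added after seeing the data. Counts of genes kept within 1.5 times the first value under 9 of the 10 other settings, the exception being the 2-fold minimum. That minimum, which leaves fewer genes by construction, gave 203 for PE at 6 h, 273 for PE at 48 h, 182 for late against early PE, 653 for JQ1 at 6 h and 981 for JQ1 at 48 h. It gave 457 for the difference of JQ1 effects, 1059 and 887 for JQ1 with PE against unstimulated cells, and 27 and 135 for genes raised by PE and lowered by JQ1 at 6 h and 48 h. Leaving out 1 array gave 3779 to 4856 genes for PE at 6 h, 5080 to 5881 for PE at 48 h, 3648 to 4562 for late against early, 6491 to 7166 for JQ1 at 6 h and 7413 to 7956 for JQ1 at 48 h. Without 1 of the 2 DMSO with PE arrays at 6 h, the other is assumed to vary like the other groups. The correlation of JQ1 effects stayed between 0.687 and 0.699 over all settings.

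An estimated inter-gene correlation changes the list test but, by construction, not the medians. With it, 0 of 11 lists passed for PE at 6 h (lowest adjusted p 0.0521) and 3 of 17 for PE at 48 h. Which part of the changed test ended the calls was not tested. For JQ1 at 6 h 0 of 13 passed (lowest adjusted p 0.176), and 6 of 16 both for JQ1 at 48 h and for the difference of effects. The JQ1 effect on genes raised or lowered by PE at 6 h kept its medians of -0.088 and 0.10 but not its calls under that setting.

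The sets of PE genes tested in the JQ1 comparison of the other time depended most on the setting, and except where given the cause was not tested. By camera with the preset correlation, genes lowered by PE at 6 h did not pass with a median of 0.090 (p = 0.0984) when the groups compared were fitted alone, nor with 0.021 (p = 0.464) under the 2-fold minimum, which tests a smaller set. Genes raised by PE at 48 h reversed to 0.00080 on repeating quantile normalization. They gave -0.34 with the 2-fold minimum (adjusted p = 3.8e-05, and adjusted p = 0.0516 with an estimated correlation). Genes lowered by PE at 48 h gave -0.074 with the groups compared alone (unadjusted camera p = 0.0342 with the preset correlation). They gave -0.061 with averaged probe sets (unadjusted camera p = 0.0407 with the preset correlation). Neither value was adjusted over the 4 sets, so neither is a call by the rule of the Results. At -0.60 with the 2-fold minimum these genes passed by camera with the preset correlation after that adjustment. Centring added 0.085 to every gene and so turned the medians of both 48 h sets positive by construction, to 0.070 and 0.017, which says nothing of these sets against other genes. With 1 array left out genes lowered by PE at 48 h ranged from -0.083 to -0.029. The lowest median came without replicate 1 of DMSO with PE at 6 h, which leaves 1 array in that group. Without replicate 1 of unstimulated cells (-0.073) or of JQ1 with PE at 6 h (-0.070), camera with the preset correlation passed only before adjustment over the sets.

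Some panel genes reversed. Nppa with JQ1 at 6 h was -0.074 on repeating quantile normalization, and -0.021 to 0.038 with 1 array left out. Myh6 with JQ1 was -0.010 at 6 h on quantile normalization. At 48 h it was -0.0017 with array weights, and -0.020 to 0.017 with 1 array left out (-0.0086 without replicate 3 of DMSO with PE at 48 h). Ccn2 with JQ1 at 6 h was 0.069 on centring, and Atp2a2 was 0.24 with averaged probe sets, which disagree. Of 871 calls of listed or panel genes, 71 were lost with at least 1 array left out and 0 changed sign. Dim genes lie closer to background, and 9229 genes remained above the dim limit.

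Replicate numbers did not pair the arrays: deviations of arrays with the same number had a median r of -0.037 over 26 pairs, 3 of them over 0.1, and 1 of 14 arrays correlated best with its own number. As a block, the number gave 4554 genes for PE at 6 h, 5606 for PE at 48 h, 6929 for JQ1 at 6 h, 7728 for JQ1 at 48 h and 4865 for the difference of effects, and the same numbers of lists (11, 17, 13, 16 and 16). Of the 871 calls of listed or panel genes, 14 were lost under the block.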

Other observations

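Several fixed lists did not pass in any of the 4 comparisons of PE or JQ1 yet held members with large changes. The test of neighbouring genes given last was written before its result was seen, but the demand that it exceed the PE comparisons was added afterwards. Glycolysis genes went both ways with 48 h of PE (11 of 24 rose and 6 fell; adjusted p = 0.196): Eno3 and the lactate transporter gene Slc16a3 rose (1.55 ± 0.047 and 1.68 ± 0.059) while Aldoc fell. JQ1 at 48 h moved these the other way for Eno3 (-1.48 ± 0.047) and Aldoc (1.62 ± 0.051). In that comparison 9 of 24 rose and 9 fell, or 9 and 10 adjusted over the list alone (adjusted p = 0.481). In the adrenergic signalling list, 9 of 28 rose and 10 fell, or 10 and 10 adjusted over the list alone with PE at 48 h (adjusted p = 0.981). Adra1b, a receptor for PE, was lower with PE at 6 h (-1.52 ± 0.058) and 48 h (-1.69 ± 0.052). JQ1 lowered Adra1b (-1.27 ± 0.058), Adra1d (-2.09 ± 0.11) and Rgs2 (-1.23 ± 0.062) at 6 h, with Prkca higher (1.58 ± 0.061; list adjusted p = 0.449). Apoptosis regulators also split (12 of 24 fell and 7 rose with JQ1 at 48 h; adjusted p = 0.261), with the caspase inhibitor gene Cflar at -1.49 ± 0.058 and Bnip3 at 0.60 ± 0.040.

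Cell types other than fibroblasts and smooth muscle showed no list call under JQ1. Of endothelial markers at 48 h, 9 of 16 fell and 1 rose (adjusted p = 0.111), with Ramp2 at -2.04 ± 0.10 and Kdr at -1.06 ± 0.12. Of epicardial and mesothelial markers, 4 of 9 fell and 1 rose (adjusted p = 0.173), with Krt18 at -2.50 ± 0.11. Of leukocyte markers, 5 of 17 fell and 0 rose (adjusted p = 0.0842). Of Schwann and neural markers, 3 of 7 fell and 1 rose (adjusted p = 0.697), and of red blood cell markers, 1 of 6 fell and 0 rose (adjusted p = 0.947). Ribosomal proteins did not pass either (2 of 17 rose and 2 fell, or 2 and 0 adjusted over the list alone; adjusted p = 0.947). The sarcomere list did not pass with JQ1 at 48 h (11 of 22 fell and 9 rose; adjusted p = 0.253), although Myl4 fell 4.84-fold (-2.28 ± 0.047) and Tcap rose (0.99 ± 0.036). For the calcium handling gene Trdn with JQ1 at 48 h, the brightest probe set gave -0.73, and of 3 others 2 fell as well (-0.53 and -0.39) and 1 rose (0.26).

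It was asked whether JQ1 moves neighbouring genes together, as an action on stretches of chromatin might. Pairs of adjacent protein-coding genes without a shared name stem numbered 8497. The JQ1 effect at 48 h correlated at r = 0.0450 (rho = 0.0390) between them, above each of 1000 permutations (two-sided permutation p = 0.001, the smallest they can give; Benjamini-Hochberg p = 0.001 over 4 comparisons). The PE comparisons gave higher values, 0.0607 at 48 h and 0.0920 at 6 h, and JQ1 at 6 h gave 0.0368, each with the same p. Neighbours therefore shared a little of their change under either treatment, and an action of JQ1 on stretches cannot be told apart from whatever neighbours share in general.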
